A study of Mus musculus with 12 samples.

How the data were processed

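Gene expression was measured on Illumina mouse BeadChip arrays, which read each transcript with probes on beads and report 1 brightness per probe. The 12 arrays fall into 4 groups of 3: colon and small intestine of mice with intact Cftr, and the same tissues of mice in which floxed Cftr was deleted by a Cre recombinase driven from the Villin promoter, active in intestinal epithelium. All mice were C57BL/6, carried intact Apc and were 3 months old, per the labels. The series design text instead words the mutant mice as deficient in Apc and Cftr, and the genotype field, which gives intact Apc, was followed. The colon samples were epithelium separated from the distal colon, although 1 protocol field speaks of whole colon tissue. The small-intestinal samples were the wall of the mid-duodenum after its villi were sheared off. The labels state that each mouse gave both tissues, but not that arrays with the same number come from the same mouse. Nothing states separate RNA preparations beyond that, so p-values measure the spread between these arrays.

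The authors deposited log2 values that had been quantile normalized over all arrays, and the 12 columns have nearly the same distribution, with medians from 7.75603 to 7.75663. The only tool named in the submitters' processing notes is limma, without a version, and the background step is not given in the sources used here. The deposited log2 values do not fall to 0 but end in a floor near 7.70, so a probe at the floor carries no transcript signal and log2 differences of dim probes are understated. A second table holds 24 columns of unnormalized signals and detection p-values, whose names match no sample's labels. Those columns were not used. The plan fixed before the data were examined had assumed such signals, with a background correction by the detection p-values, and the log2 values took their place.

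A dim-probe limit was therefore set from the values themselves. The mode of all values was 7.70 and the SD of the values below it, mirrored, was 0.0276, which put the limit at 3 SD above the mode, 7.78. A lower limit had been tried first and was dropped after the distribution of the values was seen, because it let background probes through. Probes above the limit on at least 3 arrays were kept, 22873 of 45281. Of the probes in the table, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. Symbols were checked through Entrez gene numbers, which matched 34807 probes. The probe with the highest mean over all arrays stood for its gene, which left 15996 features, made up of 12192 genes and 3804 probes without a single gene name.

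Each feature was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 12 arrays and 8 residual degrees of freedom, to which the variance prior added 2.15. The contrasts were mutant minus wild type in colon and in small intestine, the difference between these 2 contrasts, and small intestine minus colon in wild type. P-values were two-sided and adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. Beside each mean stands the SD over 3 arrays, and beside each difference the SE of the fit. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1. The number of arrays limits the precision of every value. On simulated data, 1 run per contrast changed 100 of the 15996 features by 0.5 and 100 others by 1 on the log2 scale. Of those changed by 0.5 the colon contrast recovered 90 and the small-intestinal contrast 93. Of those changed by 1 they recovered 99 and 97, and 9 of 198 and 7 of 197 calls were false. The simulated noise was independent and normal, with 1 SD per feature in all groups. It held no correlation between features and no structure between arrays. These shares therefore do not give the power or the share of false calls on the real arrays.

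Before the data were examined, 38 gene lists were fixed, 19 of pathways and gene programmes and 19 of cell type markers. They were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 38 lists, with camera at an estimated correlation and fry beside it. The genes named were also chosen by a rule fixed at that point. It takes, per genotype contrast, the 10 largest rises and 10 largest falls among features that passed and whose groups did not overlap. Where fewer passed in a direction, those with the smallest p, up to 5 in all, are given as values. Further named are 11 genes fixed in advance (Cftr, Apc, Lgr5, Ascl2, Olfm4, Axin2, Myc, Ccnd1, Muc2, Slc26a3 and Slc12a2), up to 4 members per list, the 5 largest differences per direction between tissues and the 3 smallest p-values of the difference between contrasts. Probes without a name were passed over in the prose except where stated. Genes outside the rule are named as chosen after their values were seen.

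Alternatives covered the dim-probe limit, the choice of probe, the variance prior, array weights, separate fits per tissue, the thresholds and each array left out in turn. They also covered a block for the array number, and for the number within a genotype as a stand-in for the animal. Added after seeing the data were a normexp background correction of the deposited values, a restriction to named genes, a covariate for pancreatic markers, and fits without arrays in doubt. Alternatives that need the unnormalized signals or the chip of each array were not run.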

Results

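Expression was profiled in distal colon epithelium and in villus-depleted mid-duodenum of mice lacking Cftr, the chloride and bicarbonate channel, in the intestinal epithelium, and of mice with intact Cftr. Each of the 4 groups held 3 arrays. A median of 43.2% of the probes lay above the dim-probe limit per array, a share that the quantile normalization holds nearly constant between arrays. The arrays were not equally far apart. The closest pair of all was colon wild type 1 and colon mutant 1, whose values differed with an SD of 0.0824 on the log2 scale, against 0.112 to 0.194 for pairs of 1 colon group. In small intestine, wild type 1 and wild type 3 differed by 0.104, while the pairs of 1 group reached 0.224. The labels list these 2 as separate samples but do not tie them to named mice, and were they from 1 mouse, the n of 3 and the errors of that group would not hold.

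The targeted gene was read first. The Cftr probe gave 8.02 ± 0.10 (SD, n = 3) in colon wild type and 8.11 ± 0.15 in colon mutant, a difference of 0.09 ± 0.08 (SE, limma adjusted p = 0.957). In small intestine the values were 8.22 ± 0.05 and 8.18 ± 0.11, a difference of -0.04 ± 0.08 (limma adjusted p = 0.998). A second Cftr probe was above the limit on 0 arrays. The position of these probes relative to the deleted part is not given in the sources used here, and a probe outside it checks nothing, so the arrays do not check the genotype labels.

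The tissue labels could be checked, by comparing small intestine with colon in wild-type mice. Apoa4 and Apoa1, apolipoproteins of fat-absorbing enterocytes, were higher in small intestine by 6.85 ± 0.10 (SE) and 6.68 ± 0.48 on the log2 scale. The Paneth cell defensins Defa20 and Defa3 were higher by 6.70 ± 1.17 and 6.26 ± 1.06, and Reg1 by 6.70 ± 0.07. In colon Apoa4 and Apoa1 were above the limit on 2 of 3 wild-type arrays and Defa20 and Defa3 on 1, so these sizes depend on the background level. Car1, the carbonic anhydrase of surface colonocytes, was at least 109-fold higher in colon, a bound set by the limit because it was dim on every small-intestinal array. Wfdc2 and Mptx1 were lower in small intestine by differences of -5.51 and -5.01. Saa1 and Retnlb were also lower, with fitted differences of -6.23 and -5.99, but only 1 and 2 of the 3 small-intestinal arrays lay above the limit there, so these sizes depend on the background level too. With limma, 2858 features were higher in small intestine and 3736 lower. Of 25 absorptive enterocyte markers 24 were higher and 1 lower (camera adjusted p = 3.22e-20, and adjusted p = 0.0159 with an estimated correlation). All 13 smooth muscle markers were higher (camera adjusted p = 1.28e-13, and 0.0344 as adjusted p with an estimated correlation), among them Des, by 3.20 ± 0.04. Of 20 goblet cell markers 17 were lower and 1 higher (camera adjusted p = 6.76e-08, and adjusted p = 0.00869 with an estimated correlation). Of 17 colonocyte markers 14 were lower and 1 higher (camera adjusted p = 1.69e-07), a call lost at an adjusted p = 0.0630 with an estimated correlation.

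In small intestine the question was which genes respond to loss of Cftr in the duodenal crypt compartment and wall. Aldh1a1, a retinaldehyde dehydrogenase, was 9.75 ± 0.23 (SD, n = 3) in mutant and 10.77 ± 0.13 in wild type, a fall of 2.03-fold (limma adjusted p = 0.0118). Gstm1, a glutathione transferase, was lower 1.95-fold (limma adjusted p = 0.0386). Ugt2b36, a glucuronosyltransferase, Rdh7 and Retsat, enzymes of retinoid metabolism, and the cytochrome P450 Cyp2b23 fell by 0.74, 0.74, 0.74 and 0.72 on the log2 scale, and Bbox1, the last enzyme of carnitine synthesis, by 0.72. The antimicrobial lectin Reg3a fell by 1.08 ± 0.13 (SE), the defensin Defa39 by 0.90 ± 0.15 and the sugar transporter family gene Slc5a4b by 1.14 ± 0.21. The largest rises were of Anxa4, an annexin, at 2.84-fold (limma adjusted p = 0.0478), and B3galt5, a galactosyltransferase, at 2.65-fold. The other probe of Anxa4 did not share its sign. B3galt5 had a wild-type mean of 7.904, near the dim-probe limit, so its fold depends on the background level. Gpx2, the intestinal glutathione peroxidase, rose 1.80-fold, from 13.43 ± 0.09 to 14.28 ± 0.12 (SD, n = 3, limma adjusted p = 0.0203). Tmsb10, Oxct1, Gcnt3, Errfi1, Mboat1, Chst4 and Lgals3 rose by 0.77, 0.70, 0.65, 0.63, 0.63, 0.52 and 0.46. Errfi1 is a feedback inhibitor of the EGF receptor, and Gcnt3 and Chst4 encode enzymes that build or sulfate mucin glycans. The genes named here were chosen among those whose 3 mutant arrays all lay on 1 side of the 3 wild-type arrays.

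In all, 27 features rose and 81 fell among 15996 (limma, Benjamini-Hochberg), with a median size of 0.46. An unadjusted p under 0.05 was found for 1302 features, where 799.8 would be expected. With the array number as a block, 57 features passed, 52 of the 108 among them. Fitted on the small-intestinal arrays alone, 3 features rose and 0 fell, and 1 of the 108 still passed. The joint fit takes 1 spread per feature from all 4 groups, and colon arrays vary little where a feature is at the floor. Cyp2b10, for example, had SDs of 0.0185 and 0.00342 in colon wild type and mutant, against 0.0103 and 0.283 in small intestine. For such features the joint errors and adjusted p-values are likely too small for small intestine. Of the 108, 19 were probes without a gene name, led by falls of 1.74 at ILMN_2611798 and ILMN_2457614 and rises of 1.61 at ILMN_1218006 and 1.18 at ILMN_2718570. Of the 36 features with several probes, 31 had all of them in 1 direction, the exceptions being Mxd1, Arhgef25, Aoc3, Anxa4 and Smap2. The count rested on 2 arrays: without small-intestinal wild type 1 it was 2, and without wild type 3, the array closest to it, it was 0. Without wild type 2, mutant 1, mutant 2 or mutant 3 it was 132, 113, 149 and 77, and it was 55 to 77 without any single colon array. All 108 kept their sign in each of these fits, but that says little. Leaving out a colon array cannot change a small-intestinal difference, and features chosen for a clear difference on these same arrays are unlikely to change sign. The counts depend on the spread as well as on the sizes, and wild type 1 and 3 were the closest small-intestinal pair. Pancreatic acinar markers differed between the small-intestinal arrays, with a mean of 11.4 on wild type 2, 9.94 on mutant 1 and 11.3 on mutant 2, against 8.31 to 8.48 on the remaining 3. Without those 3 high arrays, a fit chosen after seeing the data, 73 features were higher and 246 lower, 62 of the 108 among them. That fit sets mutant 3 alone, assumed to vary like the other groups, against wild type 1 and 3.

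**Figure D1:**
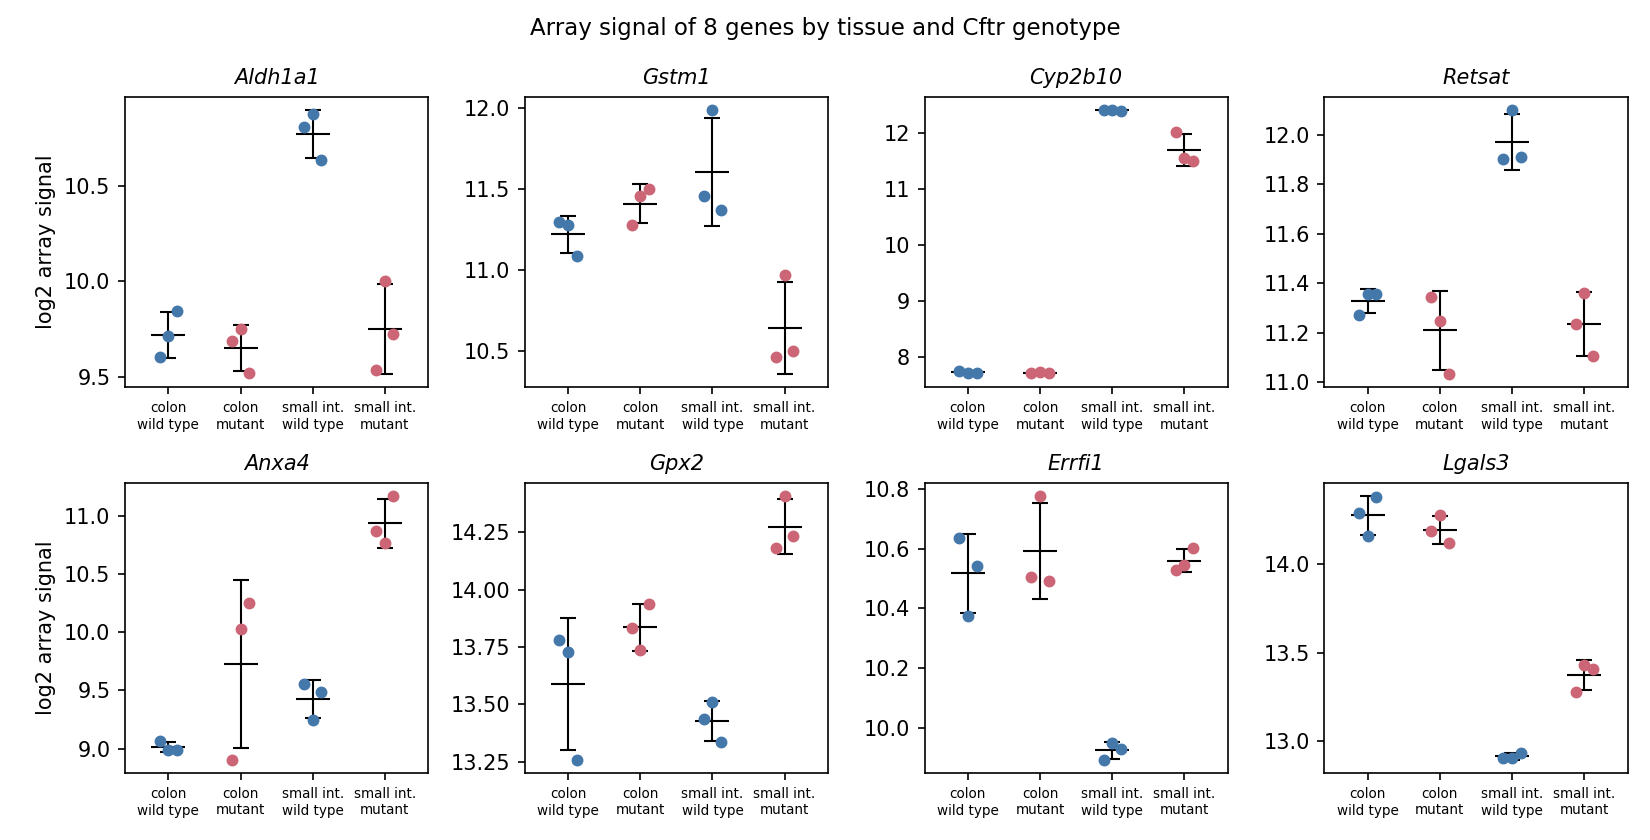
Log2 signal of 8 genes (vertical axes, which differ between panels and do not start at 0) on the 12 arrays in the 4 groups, with each array as a point and the mean ± SD of 3 arrays as a bar. Aldh1a1 lies at 9.75 in mutant and 10.77 in wild-type small intestine, and Gpx2 at 14.28 and 13.43, while no gene passed the test in colon.

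Among the lists, the xenobiotic and antioxidant genes fell as a group. Of 30 measured members 4 fell, 1 rose and 25 did not pass, and adjusted over the list alone 13 fell and 1 rose (camera adjusted p = 1.73e-08, adjusted p = 0.0176 with an estimated correlation, fry adjusted p = 0.00184). The falls were of Aldh1a1, Gstm1, Cyp2b10 and Gstm2, the last 2 by 0.71 ± 0.11 and 0.59 ± 0.10 (SE), and the rise was of Gpx2. This was the only list of 38 to pass with an estimated correlation.

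The other 11 lists that passed with the preset correlation were lost with an estimated one, and most of their members did not pass singly. Cholesterol synthesis genes shifted up, with 14 of 15 members positive, 0 passing over all features and 5 rising adjusted over the list alone (camera adjusted p = 3.86e-07, adjusted p = 0.189 with an estimated correlation). Their smallest p-values were at Hsd17b7, with 0.45 ± 0.09 (SE), and Mvd, with 0.35 ± 0.08. Immediate early and handling stress genes shifted up, with 18 of 19 positive and 0 passing (adjusted p = 5.12e-05, and 0.167 as adjusted p with an estimated correlation), and Fos differed by 0.73 ± 0.22. Their mean was 8.72 to 8.81 on the wild-type and 8.88 to 9.08 on the mutant arrays, so it moved with genotype. The falls of xenobiotic genes and the other calls moved with it, as features called between genotypes must. These values do not tell handling from another response that differs by genotype. Goblet cell markers shifted up (adjusted p = 0.0125, and adjusted p = 0.167 with an estimated correlation, fry adjusted p = 0.0138), with 0 passing, and 2 rising adjusted over the list alone, Muc2 at 0.22 ± 0.05 and Retnlb, whose wild-type mean of 7.79 lay at the limit, so that its fitted 1.64 ± 0.45 depends on the background level. Tight junction genes shifted up (adjusted p = 0.0173, and adjusted p = 0.372 with an estimated correlation) with 0 of 16 passing. Antimicrobial genes shifted up (adjusted p = 0.0370, and adjusted p = 0.256 with an estimated correlation), although Reg3a, the 1 member that passed, fell, and adjusted over the list alone 4 rose and 1 fell.

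Fatty acid oxidation and PPAR target genes shifted down (camera adjusted p = 0.0162, adjusted p = 0.167 with an estimated correlation, fry adjusted p = 0.0433). Acot1, an acyl-CoA thioesterase, fell by 0.64 ± 0.11 (SE), and adjusted over the list alone 5 fell and 1 rose. Absorptive enterocyte markers shifted down (adjusted p = 0.0337, and adjusted p = 0.516 with an estimated correlation), with Treh, which digests trehalose, falling by 0.43 ± 0.08 and 24 of 25 not passing. Paneth cell markers shifted down (camera adjusted p = 0.0370, and adjusted p = 0.582 with an estimated correlation) with 0 of 13 passing and Defa23 at -1.08 ± 0.22. On wild type 1 and 3 the Paneth mean was 11.471 and 11.439. It was 11.155 on wild type 2, within the mutant arrays at 11.09 to 11.29. Endothelial markers shifted down (adjusted p = 1.15e-04, and adjusted p = 0.220 with an estimated correlation) with 12 of 14 negative. Their mean was 8.66 on wild type 1 and on wild type 3 but 8.52 on wild type 2, within the mutant arrays at 8.46 to 8.53. Erythrocyte markers lay at 10.897 or above on wild type 1 and 3, 9.47 on wild type 2 and 9.66 to 10.2 on the mutant arrays. Adipocyte markers shifted down (adjusted p = 0.00910, and adjusted p = 0.189 with an estimated correlation), with Adipoq at -1.11 ± 0.23, and macrophage markers shifted down too (adjusted p = 0.0442, and adjusted p = 0.526 with an estimated correlation). Neither of these had a member passing over all features.

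The lists on stem cells, Wnt and growth did not pass in small intestine. Intestinal stem cell genes had 16 of 21 members negative (camera adjusted p = 0.0589), with Ascl2 at -0.12 ± 0.04 (SE), Slc12a2 at -0.31 ± 0.11 and Olfm4 at -0.34 ± 0.14. Lgr5, the crypt stem cell receptor, differed by -0.04 ± 0.06. Wnt pathway and target genes gave an adjusted p = 0.392, with Axin2 at 0.02 ± 0.10, Ccnd1 at 0.24 ± 0.14, Myc at 0.01 ± 0.03 and Apc at 0.03 ± 0.04. Slc26a3 differed by -0.01 ± 0.13. EGF receptor and MAPK output genes gave an adjusted p = 0.0543, with Errfi1 passing. Tumour suppressor and oncogenes gave 0.192 as adjusted p, with Gkn3 falling by 0.24 ± 0.04. Colonocyte markers gave an adjusted p = 0.151, with B3galt5 passing. The lists of Notch, proliferation, ion transport, interferon, MHC class II, cytokine, endoplasmic reticulum stress, circadian and sex-linked genes did not pass. Nor did those of enteroendocrine, tuft, smooth muscle, fibroblast, neural, B, T, neutrophil, mast, pancreatic, Brunner gland and erythrocyte markers. Their adjusted p-values ran from 0.192 to 0.950. In 3 lists the mean and the median differed in sign, and in 3 the mean and the test did, and none of these passed.

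In colon, 0 features passed with limma, against 818 with an unadjusted p under 0.05 where 799.8 would be expected, and the smallest adjusted p was 0.622. Among named genes, the smallest p-values of higher values were at Dbnl, with 0.20 ± 0.03 (SE), Ctss, Cd177, 1500009L16Rik and Il6st, with differences of 0.14, 0.60, 0.22 and 0.15. Among lower values they were at Uba6, with -0.38 ± 0.06, Defb37, Slc17a9, St6galnac2 and Ppp3r1, with differences of -0.75, -0.21, -0.21 and -0.23. None of the 11 genes fixed in advance passed, among them Lgr5 at -0.12 ± 0.06, Axin2 at -0.13 ± 0.10, Myc at 0.03 ± 0.03, Slc26a3 at -0.22 ± 0.13, Slc12a2 at -0.19 ± 0.11 and Muc2 at -0.04 ± 0.05. Apc, Ascl2, Olfm4 and Ccnd1 differed by -0.05, -0.02, 0.12 and 0.06.

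The absence of calls in colon rested on colon mutant 1. Without it, 31 features passed, 16 higher and 15 lower, and without wild type 1 it was 1. The mean of the immediate early and handling stress genes was 9.23 and 9.22 on mutant 2 and 3. It was 8.97 on mutant 1 and at most 8.996 on wild type. This mean separated the same arrays as the 31, which does not show that handling differed. Fos, a member, was 10.81 on mutant 2 but 10.08 on mutant 3, within the 9.91 to 10.17 of wild type. The 31 included Slpi, a secreted protease inhibitor, which was 10.87 and 10.61 on mutant 2 and mutant 3, 8.61 on mutant 1 and 8.18 to 8.61 on the wild-type arrays. Over all 3 mutant arrays Slpi differed by 1.65 ± 0.46 (SE, limma adjusted p = 0.939), and without mutant 1 by 2.36 ± 0.12 (limma adjusted p = 1.35e-04). Anxa4 was 8.91 on mutant 1, 10.03 and 10.25 on the other two, and 8.99 to 9.07 in wild type, and passed without mutant 1 at 1.12 ± 0.13. Slpi without mutant 1 and Anxa4 in colon were chosen after their values were seen.

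Proliferation genes shifted up in colon with camera (adjusted p = 7.98e-04), with 18 of 22 members positive and 0 passing, a call lost at an adjusted p = 0.882 with an estimated correlation. Bub1b, a mitotic checkpoint kinase, differed by 0.23 ± 0.08 (SE), Cdc20 by 0.27 ± 0.10 and Cdk1 by 0.21 ± 0.08. Immediate early and handling stress genes (adjusted p = 0.0229) and cytokine and NF-kB target genes (adjusted p = 0.0240) shifted up as well, with 16 of 19 members positive in each, and both were lost at an adjusted p = 0.882 with an estimated correlation. Colon mutant 2 stood apart, with means of 12.0 for erythrocyte markers and 10.4 for Paneth markers against at most 10.8 and 9.36 on the other colon arrays, and with Fos at 10.81. The other lists did not pass, with adjusted p-values from 0.0826 for macrophage markers to 0.908. Stem cell genes had 16 of 21 members negative (adjusted p = 0.0942) and Wnt genes gave 0.716. The number of lists that passed was 1 without wild type 1, wild type 2 or mutant 2, 7 without wild type 3, 8 without mutant 1 and 6 without mutant 3. It was 5 without small-intestinal wild type 2.

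**Figure D2:**
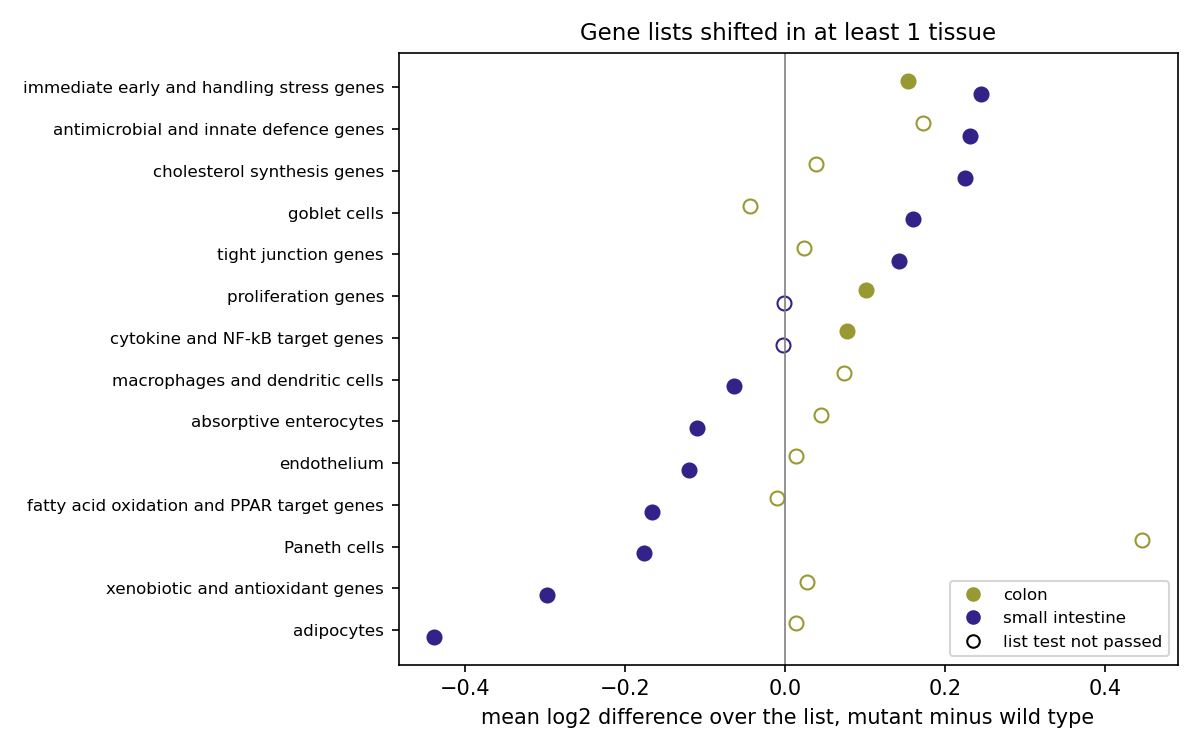
Mean log2 difference between mutant and wild type over the members of each fixed list, in colon and in small intestine, with open symbols for lists that did not pass camera with the preset correlation. Xenobiotic and antioxidant genes lie at -0.30 in small intestine and 0.03 in colon.

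Whether the tissues differed in their response was tested directly. The difference of the 2 contrasts passed for 0 features with limma, against 944 with an unadjusted p under 0.05, and the smallest adjusted p was 0.182. The smallest p was at the unnamed probe ILMN_1218006, which differed by 1.61 in small intestine and 0.03 in colon. Among named genes it was at Rbp7, a retinoid-binding protein, which differed by -0.52 in small intestine and 0.14 in colon. Next came Itga9, with -0.21 in small intestine and 0.03 in colon, and Aldh1a7, with -0.44 and 0.06. The count was 36, 20, 13 and 8 without small-intestinal wild type 2, mutant 1, mutant 2 and mutant 3, and 5 without colon mutant 1. Among the lists, xenobiotic and antioxidant genes differed between tissues by -0.32 (camera adjusted p = 1.03e-07, adjusted p = 0.0239 with an estimated correlation). Across genes, which are not independent replicates, the 2 sets of differences correlated with r = 0.0903 and rho = 0.0672. No feature passed in both tissues. Of the 108 small-intestinal calls, 68 (63.0%) had the same sign in colon and 6 had an unadjusted p under 0.05 there. Over all 15996 features, 818 had such a p in colon where 799.8 would be expected, so the 6 show no clear excess. The 68 stand without a same-sign share over all features beside them. Some of the 108 were at the floor in colon, where they cannot fall and their sign is background. In colon wild type Cyp2b10, Bbox1 and Defa39 had means of 7.715, 7.721 and 7.733. Others were well above it, with Aldh1a1 at 9.72, Gstm1 at 11.2 and Gpx2 at 13.6. At the floor a smaller response cannot be told from a lack of expression, and the tissues also differed in preparation. This limits the sign share, r and the list difference. Without colon mutant 1, 3 genes passed in both, Anxa4, Myo18b and Tfip11.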

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

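The tests of villus enterocytes, of small-intestinal tissue in colon mutant 2 and of colon mutant 1 at the small-intestinal calls were chosen after the results they bear on were seen. Of the lists, 12 had a mean genotype effect that differed between tissues by camera with the preset correlation. The difference, small intestine minus colon on the log2 scale, was -0.3246 for xenobiotic and antioxidant genes, 0.186 for cholesterol synthesis genes, 0.1183 for tight junction genes and -0.1028 for proliferation genes. Among cell type markers it was -0.1546 for absorptive enterocytes, 0.2038 for goblet cells, -0.6217 for Paneth cells, -0.1816 for fibroblasts and -0.1333 for endothelium. It was -0.1372 for macrophages and dendritic cells, -0.4523 for adipocytes and -1.08 for erythrocytes. Part of the Paneth, fibroblast and erythrocyte differences came from colon mutant 2 alone. Its means for these lists were 10.415, 8.215 and 12.002. On colon mutant 1 they were 9.353, 7.893 and 10.079, and on colon mutant 3 they were 8.989, 7.976 and 10.66. Only the first passed by camera with an estimated correlation (adjusted p = 0.0239). Members at the floor in colon, such as Cyp2b10 on that list, cannot fall there. Of 100 splits of the arrays within tissues, 6 gave as many lists as the real 12, the highest other being 14, so chance is not excluded for this count. For single genes the real count was 0, which all 100 splits reach by construction, so that comparison says nothing, and the highest other was 25.

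The features that changed in small intestine were weighed first. For pancreas carried over with the duodenum, the median feature kept 1.008 of its change with the pancreatic markers as a covariate. With it, 98 of 108 still passed. The pancreatic mean was 8.47, 11.4 and 8.48 on the wild-type arrays and 9.94, 11.3 and 8.31 on the mutant arrays. It varied widely within genotypes, so features that follow it were unlikely to be called. The kept share was therefore likely in advance and cannot decide this. For a smaller share of villus enterocytes, the median of their 25 markers was -0.02937 (SD 0.275), against -0.46 for the features that fell. Those features were chosen as falls on the same arrays and the markers were not, so part of that gap is built in. The markers ranged from -0.965 to 0.571 and showed no shared fall of that size. The list still shifted down by camera with the preset correlation, so a smaller share of these cells stays open. Of the 87 tested genes nearest to Cftr, 0 were among the 89 named calls. This argues against linked variants that change genes near the engineered locus. It does not test linked variants that act on genes elsewhere. The real split gave 108 features and 12 lists, 1 of 10 splits reached each, and the highest other gave 31 and 11, but 10 splits cannot give a share under 0.05. A response to Cftr loss stays open as a hypothesis, as does a difference in handling. The immediate early and handling stress genes separated the groups, but handling was not tested as a cause. Dependence on small-intestinal wild type 1 and 3, without which 2 and 0 features passed, stays open too. Those counts do not show whether the sizes changed.

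The second pattern is the lack of calls in colon, with colon mutant 1 closest to colon wild type 1. On the line from the wild-type mean (0) to the mean of mutant 2 and 3 (1), mutant 1 lay at 0.1459. Each wild-type array set against the mean of the other two lay at 0.128 to 0.336, mutant 1 against the same pairs at 0.155 to 0.293, and 31 features passed without it. Over the 108 small-intestinal calls its deviation from the colon wild type correlated with the small-intestinal change at r = 0.06774, against 0.420 and 0.354 for mutant 2 and 3 and -0.219 to 0.213 for each wild-type array against the other two. Both values could come from a wrong label on that array. A mouse that kept Cftr or responded weakly, or other structure unrelated to genotype, may give them too. So may a difference in handling of mutant 2 and 3. Those were the only colon arrays with a high mean of the immediate early and handling stress genes, though Fos was high on mutant 2 only. The array was used as labelled. All 10 splits reach the real 0 by construction, and 4 of 10 reached its 3 lists; the split of wild type 1, wild type 2 and mutant 1 against the rest gave 37 features and 8 lists, which points to a structure of the samples, and 10 splits cannot give a share under 0.05.

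The third pattern is colon mutant 2, with Apoa1 at 10.12, high Paneth and erythrocyte markers and Fos at 10.81. If small-intestinal tissue like that on the other arrays was the source, Apoa1 would need a share of 3.86%. The median of 13 other transcripts abundant there rose by only 0.1875 of what that share gives, and 8 of 13 by under 0.25 of it, with Apoc3 at a share of 0.203%, Cyp2b10 at 0.0104% and Apoa4, outside the 13, at 0.249%. The 13 include Amy2a5 at 0.0242% and Cela2a at -0.0973%, markers of the pancreas carried on some small-intestinal arrays, which cannot report intestinal tissue. Without them the middle transcript is ILMN_2524936, at a share of 0.890%. The values argue against tissue of that makeup, though by a narrower margin than the 13 give. Another 4 of the 13 rose by over 0.5 of it, Defa26 most at 8.66%, so tissue of another makeup and a response of that mouse stay open, neither tested.

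For the tissue comparison the real split gave 6594 features, 1 of 10 splits reached it and the highest other gave 0, which again cannot give a share under 0.05.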

How the results depend on the processing

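Of 263 alternative values of the counts reported, 205 stayed within 1.5 times or on the same side and 58 moved, and the causes were not tested unless stated. Of 8447 alternative values of single genes, 8069 stayed on the same side of the threshold, with 298 weaker, 78 stronger and 2 reversed. A change of sign counted as reversed only where the value passed in the main or the alternative fit. Genes that passed in neither could change sign and still count among the 8069. For lists, by the same rule, 1844 of 1974 stayed on the same side, with 82 weaker, 46 stronger and 2 reversed. The reversed values all concern MHC class II genes in small intestine, whose list shift ranged from -0.2616 without mutant 2 to 0.2941 without mutant 3, and was -0.3755 without the 3 small-intestinal arrays high in pancreatic markers, a fit whose mutant arm is mutant 3 alone, where H2-DMb2 was -0.2669 and H2-DMb1 -0.3715. Features raised and lowered in small intestine numbered 3 and 0 with each tissue fitted alone, which kept 1 of the 108. That fit rests on fewer arrays and takes no spread from colon, where features at the floor varied little. The numbers were 49 and 130 with array weights, and 15 and 46 with normexp. They were 11 and 20 without both colon arrays numbered 1, and 73 and 246 with mutant 3 as the only mutant array, without the 3 arrays high in pancreatic markers, values that describe that array. At an adjusted p under 0.1, 49 rose. Colon calls numbered 16 at an unadjusted p under 0.05 with at least 1.5-fold, and 23 without both colon arrays numbered 1. Genes shared between tissues were 4 and 2 in those settings. The difference between tissues' responses passed for 1 feature with a robust trended prior, 90 at the unadjusted threshold with 1.5-fold and 21 with the pancreatic covariate. It passed for 6 without both colon arrays numbered 1 and 213 with mutant 3 as the only small-intestinal mutant array. Tissue differences numbered 2013 at the unadjusted threshold with 1.5-fold. Lists shifted in colon numbered 0 without a dim-probe filter, 0 with an estimated correlation, 0 with fry and 6 with normexp, and in small intestine 1 with an estimated correlation and 3 with fry. The normexp, covariate and set-aside fits were chosen after seeing the data.

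With each array left out in turn, the small-intestinal rises ranged from 0 to 49, the falls from 0 to 110, colon calls from 0 to 31, interaction calls from 0 to 36 and tissue differences from 5716 to 6735. Shared calls ranged from 0 to 3, lists in colon from 1 to 8 and lists in small intestine from 8 to 14. The Cftr difference ranged from 0.0453 to 0.181 in colon and from -0.106 to -0.0113 in small intestine. An arm left with 2 arrays, or with 1, is assumed to vary like the other groups. All 108 small-intestinal features kept their sign wherever they were tested, which their choice from the same arrays made likely in advance. Same-numbered arrays of 1 genotype, which could share a mouse, correlated at -0.042 to 0.162 between tissues. Between genotypes, which cannot share a mouse, they correlated at 0.0461 to 0.373 in small intestine and -0.208 to 0.137 in colon. Of 12 arrays, 6 matched their own number best, a count without a chance level beside it. The numbers thus showed no clear pairing by mouse. With the number as a replicate block, 17 features rose and 40 fell in small intestine. With the number within a genotype as a random block, standing in for the animal, 27 and 80 did. Its correlation of 0.0423 does not measure an effect of the animal, since numbers are not tied to mice. Alternatives on the unnormalized signals, detection p-values and the chip as a block were not run. Signal near the floor limits what can be seen at dim genes such as Cftr, Lgr5, Myc and Ascl2.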

Other observations

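Some single members of the fixed lists differed in small intestine without passing over all features. Retnlb, a goblet cell product abundant in colon, was 9.43 ± 0.36 (SD, n = 3) in mutant and 7.79 ± 0.02, at the limit, in wild type (limma adjusted p = 0.224). Duox2, an oxidase of the epithelial surface, was 8.46 ± 0.24 against 7.92 ± 0.08 (limma adjusted p = 0.0551), and Dmbt1, a mucosal scavenger glycoprotein, 14.17 ± 0.07 against 13.56 ± 0.04 (limma adjusted p = 0.173). Scd1, a fatty acid desaturase, was 8.06 ± 0.17 against 9.52 ± 0.86 (limma adjusted p = 0.115). In each, the 3 mutant arrays lay on 1 side of wild type. Dusp6, a MAP kinase phosphatase, differed by 0.66 ± 0.14 (SE, limma adjusted p = 0.0853).

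Among the 31 colon features that passed without colon mutant 1 were rises of Dlk1 at 0.93 ± 0.09 (SE), Ly6g6c at 0.88 ± 0.10, Cyp2d9 at 0.87 ± 0.06, Capg at 0.87 ± 0.12 and Fut2 at 0.66 ± 0.08. Falls included Gfpt1 at -0.89 ± 0.10, Nrep at -0.61 ± 0.09 and Pigt at -0.59 ± 0.07. These were chosen after their values were seen. The Y-linked gene Eif2s3y lay between 8.87 and 9.22 on the 12 arrays and Xist between 7.71 and 7.81.

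A hypothesis on the fall of xenobiotic genes is lower activity of CAR, the nuclear receptor that drives Cyp2b10. Of 47 listed CAR targets, 14 were measured, not on the fixed list and not called singly. Their mean difference in small intestine was -0.2612 (SD 0.313), with 10 of 14 negative and p = 0.0105 by camera with an estimated correlation. In colon the mean was -0.06 and the same camera test by limma gave a p of 0.415. The values are consistent with lower CAR activity, but other receptors share these targets. The transcript of the receptor, Nr1i3, differed by -0.15 ± 0.09 (SE, limma adjusted p = 0.776), which does not measure its activity, so this stays a hypothesis.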
